A study of Mus musculus with 32 samples.

How the data were processed

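Total RNA from 32 lymphomas of Eµ-myc transgenic mice had been converted to biotin-labelled cRNA by in vitro transcription and hybridised to Affymetrix Mouse430_2 arrays, per the labels' protocols, with 1 array per tumour. The deposited values are log2 expression values per probe set, made by the authors with RMA in the affy package, per the submitters' processing notes. RMA corrects background, makes the distribution of all arrays equal and summarises the probes of a set. It brings arrays to a common scale and would hide a shift shared by most genes. Versions and parameters of that processing are not given in the sources used here, and scanner files were not used here. The log2 scale was checked on the values, whose array medians lay between 5.72 and 5.80. All 32 columns were mapped to a tumour by their sample, and 0 columns were left over.

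Of 45101 probe sets, 34958 had 1 gene symbol in the platform annotation given, 932 had several and 9211 had none. Names were taken only from probe sets with 1 symbol, and the Entrez identifiers of 34741 of them were found in the RefSeq genes of assembly GRCm38.p6, which changed 0 symbols. That table also gave each gene's chromosome. The main setting kept probe sets with a mean at or above the median of all probe set means (5.78) and took the probe set with the highest mean for each gene, which left 11227 genes. No level of a probe set was set against that of another. Members of a list without a probe set of their own name, or named only together with other genes, are not analysed here.

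Tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Since the labels give 1 group, no groups were compared and no sample was left out of the main results. Spread was the SD over the tumours. The 23 gene lists were precursor B cell, mature B cell, genes shared by B cell stages, germinal centre, plasma cell, NF-kB, Myc targets, proliferation, p53 targets, Bcl2 family, interferon, T cell, NK cell, myeloid, stroma, endothelial, erythroid, oxidative phosphorylation, glycolysis, hypoxia, early stress, sex-linked and reference genes. A list's median SD and mean pairwise r were given as percentiles among 10000 random lists of the same size drawn from 20 bins of mean level, as a description, since genes are not replicates. The score of a list in a tumour was the mean over its tested genes of the standardised log2 value, for lists with at least 3 tested genes.

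Relations were tested with Pearson's r and Spearman's rho and two-sided permutation tests of 100000 resamples, with Benjamini-Hochberg adjustment within 3 families (the 20 planned relations, RNA quality, and components). Each r was computed again without the 2 tumours farthest from the median of the x measure. A measure with a gap of at least 25% of its range and at least 3 tumours on each side counted as clustered, and r was then taken within a cluster of at least 6 tumours. RNA quality was the 3' minus 5' difference of the Gapdh and Actb control probe sets. Batches could not be tested, since the sources used here name none.

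Genes associated with 4 continuous axes (the precursor B cell score, the proliferation score, and the Cdkn2a and Myc levels, each scaled to an SD of 1) were found with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05), leaving out the axis genes. Lists were tested with camera, with a preset correlation of 0.01 and with an estimated one. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Named genes were the 25 with the largest SD, the 12 rising and 12 falling genes with the largest moderated t on each axis, list members (those with the 2 largest and 2 smallest SDs, or examples along an axis), and the genes of the relations.

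The steps were tested on simulated data. Of 500 random pairs 3.8% had a permutation p under 0.05, and of 500 pairs with a true r of 0.6, 95.6% did. With 200 of 11227 simulated genes following an axis, limma recovered 26%, 21%, 14% and 19% of those with a slope of 0.5 gene SDs on the precursor, proliferation, Cdkn2a and Myc axes, and 97%, 97%, 91% and 98% of those with a slope of 1 gene SD. Of the genes called, 6.82%, 4.84%, 0.943% and 5.65% were false on these axes in turn. All 4 planted chromosome shifts were found, with 0 others. Simulated genes varied independently of each other, unlike measured genes, so the limma and chromosome rates need not hold for these data. Of 60 random lists of measured genes, the median percentile was 58.95 for the SD and 37.35 for r.

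The alternatives were the mean of a gene's probe sets, no filter, a filter at the 75th percentile, arrays shifted by the reference genes, quantile normalization again, each tumour left out in turn, an SD from the median absolute deviation, the 3' minus 5' difference or the mean of the T cell, myeloid and stroma scores as a covariate, the first component as a list score, Spearman's rho, ranks of the axis, and robust and trended eBayes. Chosen after seeing the data were the results without the 11 tumours of the upper Bpifa2 cluster, without the 2 tumours with the highest T cell score and without the upper Cdkn2a cluster, and the analysis of chromosomes.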

Results

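Lymphomas of mice that carry the Eµ-myc transgene were profiled on 32 Affymetrix Mouse430_2 arrays, with 1 array for each tumour. In this model the immunoglobulin heavy chain enhancer drives the Myc oncogene in cells of the B lineage. The labels give 1 group and no control group, so the measurements describe how the tumours differed from each other, and no comparison between groups was made. Tumours are named here by their number in the labels, from 1 to 32. RNA came from tumour tissue or from dissociated tumour cells, and the labels do not say which applied to a given tumour. They also do not say whether any 2 tumours came from the same mouse. The tests treated the 32 tumours as independent, and the p-values may be too small if some were not. With 1 array per tumour, differences between tumours may in part be technical. The array medians lay between 5.72 and 5.80 on the log2 scale, 0 pairs of arrays held identical values, and 11227 genes were tested. The number of arrays limits the precision of every value.

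Bpifa2, which encodes a protein secreted by salivary glands, had the largest SD over the tumours (4.73 on the log2 scale, n = 32). Its value was between 12.97 and 14.26 in 11 tumours (3, 4, 9, 12, 15, 16, 18, 20, 25, 29 and 30) and at most 5.19 in the other 21. The same 11 tumours stood above a gap in 7 more of the 25 most variable genes, namely the amylase gene Amy1 (SD 4.38), Smr3a (SD 4.02), the secreted carbonic anhydrase Car6 (SD 3.78), the prolactin-inducible protein gene Pip (SD 3.75), Cst10 (SD 3.55), the chitinase gene Chia1 (SD 3.52) and 2310057J18Rik (SD 3.46). Dnase1 (SD 3.69), Dcpp3 (SD 2.55), Scgb1b27 (SD 2.44) and Wfdc12 (SD 2.23) were also among the 25.

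The sex-linked list had 2 tested genes. Xist, the RNA that coats the inactive X chromosome, was between 12.62 and 13.69 in 18 tumours and between 6.28 and 6.93 in the other 14. The Y-linked gene Eif2s3y was between 7.04 and 10.23 in 14 tumours and between 3.41 and 4.28 in 18. No tumour was high in both genes and none was low in both. Genes of immunoglobulin assembly also ranked among the 25. Rag1, which cuts immunoglobulin genes for recombination, ran from 3.38 in tumour 30 to 12.02 in tumour 25 (SD 2.84, n = 32). Vpreb1, a part of the surrogate light chain, was between 11.17 and 12.43 in 5 tumours and at most 8.03 in the other 27. The immunoglobulin genes Jchain, Iglv1 and Igha had SDs of 2.50, 2.35 and 2.25. The remaining genes among the 25 were Reln (SD 2.64), Cpn1 (SD 2.52), Hepacam2 (SD 2.44), Car3 (SD 2.41), Kcnk1 (SD 2.37) and Gm6958 (SD 2.23).

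Of the 11227 genes, 380 (3.38%) had an SD over 1 and 31 an SD over 2, and the median SD was 0.28. With the SD taken from the median absolute deviation, which a few high tumours move less, 236 genes exceeded 1. With the stricter filter on dim probe sets, which left fewer genes, 146 did. The 9 hybridisation control probe sets, which read the same spiked RNA on every array, had SDs from 0.07 to 0.22, and 69.5% of the genes lay above the highest of these. The 12 poly-A control probe sets, which pass through the labelling as well, had SDs from 0.31 to 0.37, and 32.1% of the genes lay above the highest. Different probe sets of a gene had a median r of 0.67 over the tumours (4840 genes), and of 0.95 for the 109 of these genes with an SD over 1.

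**Figure D1:**
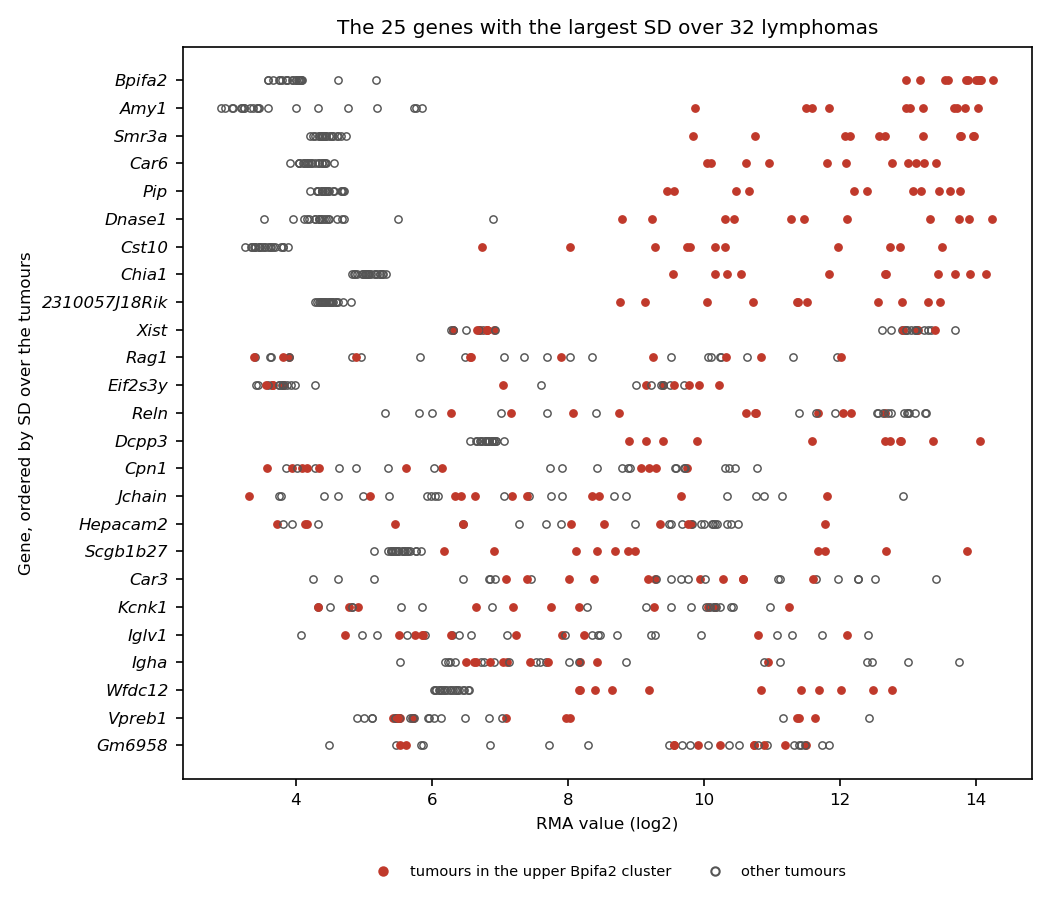
RMA values (log2, x axis) of the 25 genes with the largest SD (y axis) in each of the 32 lymphomas, 1 point per tumour, with the 11 tumours of the upper Bpifa2 cluster filled. Bpifa2 was at least 12.97 in the filled tumours and at most 5.19 in the others.

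Genes that mark stages of B cell development differed widely between tumours. Of the 13 tested genes of the precursor B cell list, 10 had an SD over 1, and the list's median SD of 1.34 was above that of every one of the 10000 random lists matched on level, whose median was 0.28. Rag1 and Vpreb1 had the largest SDs (2.84 and 2.23), and the receptor kinase genes Flt3 and Kit the smallest (0.45 and 0.55). The members moved together to a limited degree, with a mean pairwise r of 0.18 at percentile 99.98 of the random lists. The score of the list was highest in tumour 25 and lowest in tumour 24. The mature B cell list, which holds antigen presentation genes and receptors of resting B cells, had a median SD of 0.87 (percentile 100) and a mean r of 0.35 (percentile 100), with Fcmr and the CD20 gene Ms4a1 as the most variable members (SD 1.76 and 1.74) and Ccr7 and Cd40 as the least (SD 0.43 and 0.55). Genes shared by most B cell stages varied less, with a median SD of 0.45 (percentile 99.94) and a mean r of 0.27 (percentile 99.83). In that list the kinase gene Blk and Cd72 had the largest SDs (1.31 and 0.83), and Btk and Pou2af1 the smallest (0.25 and 0.32).

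The germinal centre list had 4 tested genes, a median SD of 0.67 (percentile 97.8) and a mean r of 0.49 (percentile 99.95). Bcl6, the repressor that sets the germinal centre programme, had an SD of 1.12, Lmo2 of 0.80, Fas of 0.54 and S1pr2 of 0.33. Tumour 2 weighed heavily in these values. It was the highest in Bcl6 (10.90, with 8.11 next), Lmo2 (10.89, with 10.24 next) and S1pr2 (9.22, with 7.87 next), and in Fas (7.87) it came next to tumour 24 (7.98). The list's spread and mean r without tumour 2 are not given here. The plasma cell list had a median SD of 0.69 (percentile 99.7) and a mean r of 0.18 (percentile 93.0). Jchain and Sdc1 varied most in it (SD 2.50 and 1.22), and Xbp1 and Irf4 least (SD 0.52 and 0.66).

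Markers of cells other than the lymphoma differed between tumours as well. The T cell list had 7 tested genes, of which 4 had an SD over 1, a median SD of 1.12 (percentile 99.99) and a mean r of 0.75 (percentile 100). The T cell receptor chain genes Cd3g and Cd3d had SDs of 1.69 and 1.39, and Icos and Cd4 of 0.54 and 0.69. Tumours 24 and 2 had the highest T cell scores. The myeloid list had a median SD of 0.85 (percentile 100) and a mean r of 0.46 (percentile 100), led by the neutrophil genes S100a9 and S100a8 (SD 2.05 and 1.96), with Lgals3 and Cd68 at the low end (SD 0.64 and 0.67). The stroma list of matrix genes had a median SD of 0.92 (percentile 100) and a mean r of 0.62 (percentile 100), with Col3a1 and Lum (SD 1.13 and 1.10) at the high end and Col6a1 and Sparc (SD 0.52 and 0.67) at the low end. The endothelial list had a median SD of 0.50 (percentile 94.2) and a mean r of 0.55 (percentile 100), with Emcn and Cdh5 (SD 0.64 and 0.54) varying most and Kdr and Eng (SD 0.35 and 0.41) least. The NK cell list had 2 tested genes, Nkg7 (SD 1.22) and Prf1 (SD 0.45). None of the erythroid list's genes passed the filter on dim probe sets, and 7 of its 10 members had a dim probe set only.

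Interferon-induced genes had a mean r of 0.81 over the tumours (percentile 100) and a median SD of 1.01 (percentile 100). Cxcl10 and Ifit1 had the largest SDs (1.32 and 1.17), and Ddx58 and Irf9 the smallest (0.44 and 0.45). Their score stood above a gap in tumours 2, 10 and 24. The NF-kB list, which holds targets and subunits of that transcription factor family, had a mean r of 0.63 (percentile 100) and a median SD of 0.66 (percentile 99.95), with Cd83 and Tnfaip3 (SD 1.11 and 0.91) varying most and Rel and Nfkbia (SD 0.41 and 0.44) least. Early stress genes had a median SD of 0.83 (percentile 99.89) and a mean r of 0.33 (percentile 99.98), with Egr1 and Hspa1b (SD 1.29 and 0.996) at the high end and Ier2 and Jun (SD 0.44 and 0.65) at the low end. Hypoxia genes had a median SD of 0.59 (percentile 96.5) and a mean r of -0.02 (percentile 42.1), and so did not move together. Ankrd37 and Bnip3 varied most in that list (SD 0.83 and 0.78), and P4ha1 and Vegfa least (SD 0.45 and 0.47).

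Growth genes moved together over the tumours. The 17 Myc target genes, mostly genes of ribosome assembly and nucleotide synthesis, had a median SD of 0.25 (percentile 88.7) and a mean r of 0.50 (percentile 100), with Srm and Cdk4 (SD 0.42 and 0.41) varying most and Npm1 and Ncl (SD 0.08 and 0.11) least. The proliferation list had a median SD of 0.28 (percentile 88.6) and a mean r of 0.35 (percentile 100), with Tyms and Rrm2 (SD 0.59 and 0.57) and Mki67 and Cdc20 (SD 0.18 and 0.20) at the ends. The p53 target list had a median SD of 0.40 (percentile 98.0) and a mean r of 0.13 (percentile 98.8). Zmat3 and Cdkn1a varied most in it (SD 1.25 and 0.89), and Rps27l and Mdm2 least (SD 0.14 and 0.18). The Bcl2 family list, with regulators of apoptosis of opposite action, had a median SD of 0.29 (percentile 51.8) and a mean r of 0.03 (percentile 77.5), with Bcl2 and Bmf (SD 0.98 and 0.91) and Hrk and Bad (SD 0.09 and 0.24) at the ends. Glycolysis genes had a median SD of 0.28 (percentile 86.1) and a mean r of 0.43 (percentile 100), with Hk2 and Slc2a1 both at an SD of 0.45 and Pgk1 and Ldha at 0.16 and 0.18. Genes of oxidative phosphorylation had a median SD of 0.18 (percentile 14) and a mean r of 0.32 (percentile 99.94), from Atp5a1 and Sdha (SD 0.23 and 0.22) to Cox5a and Cox5b (SD 0.08 and 0.10). The reference genes had a median SD of 0.15 (percentile 6.87) and a mean r of -0.01 (percentile 33.1), from Tbp and Ywhaz (SD 0.21 and 0.16) to Rplp0 and Actb (SD 0.05 and 0.08).

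**Figure D2:**
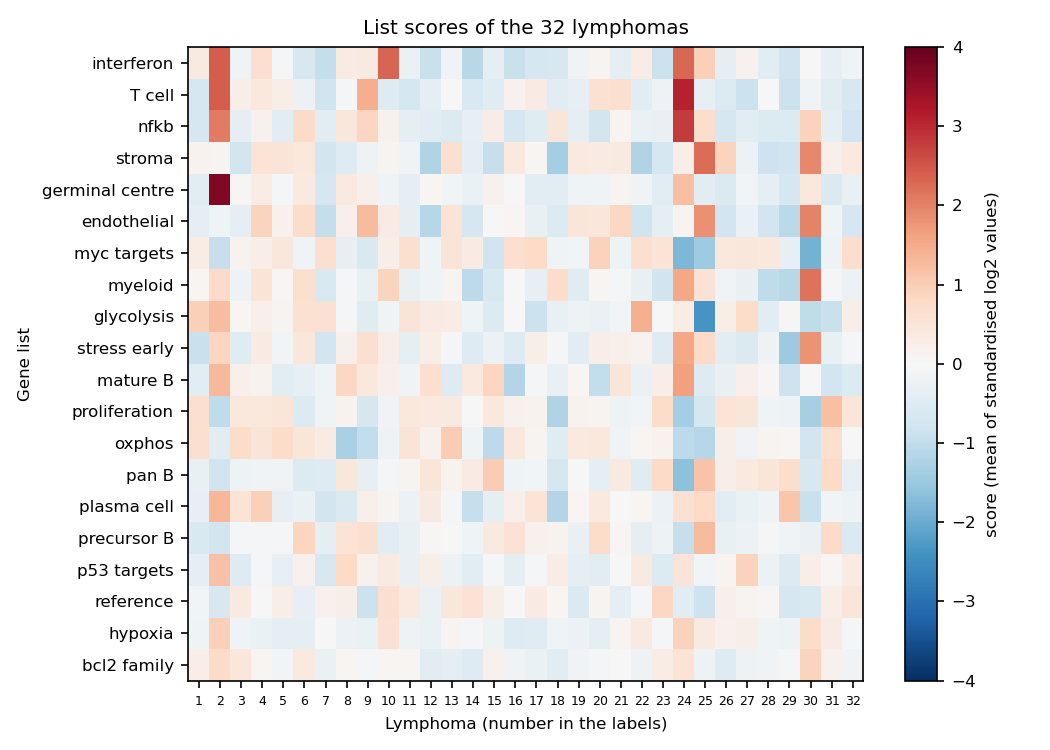
Scores of the gene lists (y axis) in the 32 lymphomas (x axis), each score being the mean over a list's tested genes of the log2 value standardised over the tumours, with red above and blue below 0. The highest T cell score was 3.08 in tumour 24 and the highest germinal centre score 3.71 in tumour 2.

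Myc itself had a mean of 11.34 ± 0.50 (SD, n = 32), and its level followed the score of its target genes across tumours (r = 0.55, raw p = 0.00158, adjusted p = 0.00497; rho = 0.59, p = 0.00047; permutation tests, two-sided, n = 32). Without the 2 tumours farthest from the median Myc level r was 0.50. The relation did not pass with the mean score of T cell, myeloid and stroma markers as a covariate (r = 0.34, adjusted p = 0.105) or without the 2 tumours with the highest T cell score (r = 0.42, adjusted p = 0.0561). Here and below, adjusted values are over the 20 planned relations, of which 10 passed, 8 of them positive. The Myc target score also followed the proliferation score (r = 0.66, raw p = 0.00012, adjusted p = 0.00107; rho = 0.47, p = 0.00667), with r = 0.47 without the 2 far tumours.

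Cdkn2a, which encodes p16Ink4a and p19Arf, fell into clusters. It was between 10.70 and 10.79 in tumours 7, 14 and 23 and between 3.79 and 8.51 in the other 29. Within those 29 tumours Cdkn2a followed the score of p53 target genes (r = 0.55, raw p = 0.00174, adjusted p = 0.00497; rho = 0.58, p = 0.00128), with r = 0.55 without the 2 far tumours. With the stricter filter on dim probe sets it did not pass (r = 0.39, adjusted p = 0.0619). The p53 target scores of tumours 7, 14 and 23 were -0.63, -0.45 and -0.55, at ranks 1, 6 and 2 from the lowest of the 32, and the relation cannot be tested among 3 tumours. Cdkn2a and the Myc target score were not related within the 29 (r = 0.11, raw p = 0.567, adjusted p = 0.667; rho = 0.10, p = 0.617), with r = 0.14 without the 2 far tumours.

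The Bcl2 and Mcl1 genes, whose proteins both block apoptosis, rose and fell together (r = 0.62, raw p = 0.00016, adjusted p = 0.00107; rho = 0.64, p = 0.00011), with r = 0.59 without the 2 far tumours. The stroma and endothelial scores did so too (r = 0.74, raw p = 1e-05, the smallest that the permutations can give, adjusted p = 0.0002; rho = 0.65, p = 0.00012), with r = 0.55 without the 2 far tumours, as did the germinal centre and NF-kB scores (r = 0.73, raw p = 0.00025, adjusted p = 0.00125; rho = 0.54, p = 0.00151), with r = 0.56.

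**Figure D3:**
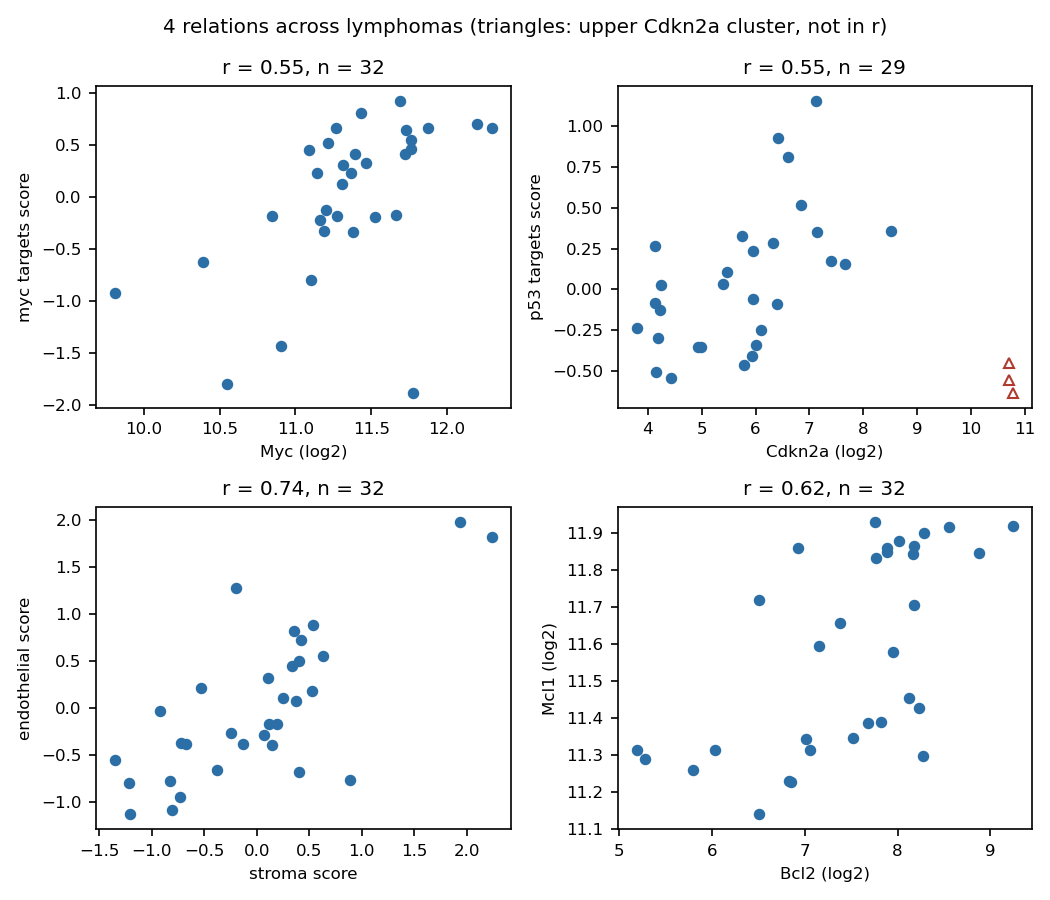
Each panel plots 2 measures against each other, 1 point per lymphoma, with gene levels in log2 and list scores in units of standardised values. The 3 open triangles are the upper Cdkn2a cluster, left out of that panel's r, and r was 0.55 for Myc, 0.55 for Cdkn2a, 0.74 for stroma and 0.62 for Bcl2.

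The other 4 relations that passed rested on few tumours. The T cell score was related to the myeloid score (r = 0.43, raw p = 0.0178, adjusted p = 0.0357; rho = 0.42, p = 0.018), to the score of genes shared by B cell stages (r = -0.56, raw p = 0.00092, adjusted p = 0.00368; rho = -0.30, p = 0.0993) and to the proliferation score (r = -0.50, raw p = 0.00412, adjusted p = 0.0103; rho = -0.32, p = 0.0728). Without the 2 tumours farthest from the median of the x measure, r was 0.15, -0.36 and -0.18. Leaving out tumour 24 alone ended all 3 calls (r = 0.26, -0.36 and -0.35), and leaving out tumour 2 or tumour 29 ended the myeloid call (r = 0.40 and 0.41). The stroma score was related to the early stress score (r = 0.46, raw p = 0.00923, adjusted p = 0.0205; rho = 0.32, p = 0.0739), with r = 0.21 without the 2 far tumours, r = 0.31 without tumour 30 and r = 0.18 without the 11 tumours of the upper Bpifa2 cluster.

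The precursor and mature B cell scores ran opposite without passing the adjusted threshold (r = -0.37, raw p = 0.0351, adjusted p = 0.0542; rho = -0.23, p = 0.215), with r = -0.34 without the 2 far tumours. Proliferation with p53 targets (r = -0.36, raw p = 0.0406, adjusted p = 0.058; rho = -0.27, p = 0.141), interferon with myeloid genes within 29 tumours (r = 0.39, raw p = 0.0352, adjusted p = 0.0542; rho = 0.43, p = 0.0225) and oxidative phosphorylation with glycolysis (r = 0.38, raw p = 0.0315, adjusted p = 0.0542; rho = 0.34, p = 0.0576) also lay just outside it. Without the 2 far tumours these r were -0.29, 0.29 and 0.23. Each of the 4 passed when certain single tumours were left out. These were tumour 1, 8, 9, 15, 22 or 32 for the B cell scores (r from -0.44 to -0.39), 8, 27 or 31 for proliferation with p53 targets (r from -0.45 to -0.39), 6, 9, 18, 22, 27 or 30 for interferon with myeloid genes (r from 0.41 to 0.46), and 2, 8, 17, 22, 24, 27 or 31 for oxidative phosphorylation with glycolysis (r from 0.39 to 0.45).

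Ighm, which encodes the heavy chain of immunoglobulin M, was related neither to the precursor score (r = -0.02, raw p = 0.893, adjusted p = 0.939; rho = -0.12, p = 0.502) nor to the mature score (r = 0.01, raw p = 0.939, adjusted p = 0.939; rho = 0.26, p = 0.144), with r of -0.20 and 0.27 without the 2 far tumours. The relation to the mature score passed without tumour 2 (r = 0.44, adjusted p = 0.0272). Mdm2 and Cdkn1a, both p53 targets, were not related (r = 0.14, raw p = 0.462, adjusted p = 0.577; rho = 0.05, p = 0.785), with r = 0.20 without the 2 far tumours. Interferon and T cell genes within 29 tumours did not pass (r = 0.27, raw p = 0.154, adjusted p = 0.206; rho = 0.22, p = 0.243), with r = 0.28. Hypoxia and glycolysis did not pass either (r = 0.05, raw p = 0.763, adjusted p = 0.848; rho = 0.13, p = 0.482), with r = -0.18 without the 2 far tumours, and the first component as the list score gave the opposite sign (r = -0.52, adjusted p = 0.00424). The 3' minus 5' difference of the control transcripts, a sign of RNA degradation, ran from 0.26 to 0.96. None of the 20 list scores was related to it after adjustment, over all tumours or, for the clustered interferon score, within the 29 without tumours 2, 10 and 24. The lowest raw p was that of the reference genes (r = -0.42, raw p = 0.015, adjusted p = 0.225; rho = -0.33, p = 0.0642), with r = -0.27 without the 2 far tumours. Without the 2 tumours farthest from the median of the score in question, r rose for the T cell score (0.20, raw p = 0.246, adjusted p = 0.846; rho = 0.38, p = 0.0328) to 0.56 (unadjusted p = 0.003), and for the endothelial score (0.40, raw p = 0.0225, adjusted p = 0.225; rho = 0.29, p = 0.112) to 0.46 (unadjusted p = 0.00903).

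Across the tumours, 259 genes were associated with the precursor B cell score in limma, 159 rising and 100 falling with it. Slopes are given as log2 change per SD of the score ± SE (n = 32), and on each axis genes are named in the order of the moderated t, not of the slope. The risers with the largest t were Zkscan17 (0.41 ± 0.04, adjusted p = 2.36e-07), Fam53b (0.55 ± 0.08), Znrf1 (0.35 ± 0.05), Cmtm7 (0.40 ± 0.06) and the tyrosine kinase gene Abl1 (0.26 ± 0.04), followed by Cpm, Stambpl1, Pde2a, 4933439C10Rik, Tspan6, Gpsm1 and the histone deacetylase gene Hdac7 (0.21 to 0.84). Of the falling genes, Txndc5, which encodes a disulfide isomerase of the endoplasmic reticulum, had the largest t in size (-0.43 ± 0.06, adjusted p = 6.2e-05), followed by Lactb, AI413582, Swap70, C430042M11Rik, Ryk, Naaa, Dclre1a, Ankrd37, Cdc14b, Ints4 and Mif4gd (-0.59 to -0.25).

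Few list members passed with the precursor score. Ankrd37 (-0.59 ± 0.10, adjusted p = 0.00125) and P4ha1 (-0.28 ± 0.06, adjusted p = 0.0126) of the 6 hypoxia genes fell, and 0 genes of the other lists passed over all genes tested. Adjusted over the list alone, 7 of 8 glycolysis genes and 2 of 14 mature B cell genes fell, and 5 of 10 genes shared by B cell stages and 2 of 7 endothelial genes rose. With a preset correlation, camera placed the glycolysis (adjusted p = 9.29e-05), mature B cell (0.00571) and interferon (0.00571) lists lower and the endothelial list (0.00191) and the list of genes shared by B cell stages (0.00291) higher. With an estimated correlation the adjusted p was 0.231, 0.556, 0.809, 0.405 and 0.405, and no list passed with an estimated correlation on this or any of the other 3 axes. The count fell to 125 without tumour 31 and to 156 without the 11 tumours of the upper Bpifa2 cluster, and it rose to 952 without the 2 tumours with the highest T cell score and to 410 with the score of other cell types as a covariate. With arrays shifted by the reference genes the share of rising genes went from 61.4% to 72.5%, and the medians of the hypoxia and plasma cell lists changed sign. The plasma cell list had a median slope of -0.02 where camera placed it up, and the myeloid list a median of -0.10 with a mean of 0.02.

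With the proliferation score, 3126 genes were associated, 1984 rising and 1142 falling. The risers with the largest t were the cytokinesis gene Anln (0.27 ± 0.03, adjusted p = 2.01e-07), the cyclin gene Ccnf (0.30 ± 0.03), the centromere gene Cenpi (0.19 ± 0.02), Hirip3 (0.39 ± 0.04), the kinesin gene Kif18b (0.20 ± 0.02) and the kinetochore genes Spc25 (0.22 ± 0.03) and Zwilch (0.28 ± 0.04). Ftsj1, BC055324, Cenpx, Tbcc and the heterochromatin gene Cbx5 followed (0.22 to 0.29). Sidt2 (-0.26 ± 0.03, adjusted p = 3.49e-06), the chemokine gene Cxcl16 (-0.45 ± 0.06) and Gng12 (-0.52 ± 0.07) had the largest t in size among the falling genes, followed by Rnf217, Ptpre, Snx18, P2rx4, Scarb2, Rgs1, Pld1, Gpr137b and Gpr137b-ps (-0.88 to -0.28). Gpr137b-ps is a pseudogene of Gpr137b, and signal shared between their probe sets was not tested.

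All 10 NF-kB genes fell as the proliferation score rose, with Tnfaip3 (-0.68 ± 0.11, adjusted p = 6.56e-05) and Bcl3 (-0.50 ± 0.09, adjusted p = 0.000174) having the lowest p. The list passed camera with a preset correlation (adjusted p = 5.64e-09) but not with an estimated correlation (adjusted p = 0.0953). Of the 17 Myc target genes 11 rose, among them Nop56 (0.19 ± 0.04) and Bop1 (0.24 ± 0.05), and 14 rose adjusted over the list alone (camera adjusted p = 5.69e-05, and 0.29 with an estimated correlation). With arrays shifted by the reference genes, 3 of these 17 rose and 8 of the 10 NF-kB genes fell. The other lists that passed with a preset correlation were myeloid, T cell, interferon, early stress, mature B cell, endothelial and germinal centre genes, placed lower, and oxidative phosphorylation genes and genes shared by B cell stages, placed higher (adjusted p from 8.14e-06 to 0.0493). Of 10 genes shared by B cell stages 5 rose, among them Cd79b (0.19 ± 0.05). Markers of other cell types fell along the same axis: 7 of 13 myeloid genes, such as Csf1r (-0.60 ± 0.11), 4 of 7 T cell genes, such as Cd3e (-0.34 ± 0.11), 2 of 9 stroma genes and 1 of 7 endothelial genes. Early stress genes (4 of 6), interferon genes (3 of 10), hypoxia genes (2 of 6), mature B cell genes (2 of 14) and germinal centre genes (1 of 4) fell as well. Shifting the arrays by the reference genes left 7 myeloid, 2 T cell, 1 stroma, 3 early stress and 1 interferon gene falling. It left 3 genes shared by B cell stages rising. In the precursor list Kit and Flt3 fell and Vpreb3 and Myb rose, and camera's direction was down while the median slope was 0.20. Of 12 oxidative phosphorylation genes 3 rose, and of 5 plasma cell genes 1 rose, but 0 of either list did with arrays shifted by the reference genes. Of 8 glycolysis genes 2 rose and 1 fell, and the reference genes Tbp and Hprt rose, but with arrays shifted by the reference genes 0 genes of either list passed and both medians changed sign. None of the p53 target or Bcl2 family genes passed. The count was 1287 with the score of other cell types as a covariate, 1822 with ranks, 1743 without the upper Bpifa2 cluster and 1613 with arrays shifted by the reference genes, where 44.1% of the genes rose in place of 63.5%.

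With the level of Myc, 2257 genes were associated, 1171 rising and 1086 falling. Mcoln2 had the largest t among the rising genes (0.48 ± 0.06, adjusted p = 1.31e-05), followed by Pde12 (0.18 ± 0.02), Pus7 (0.31 ± 0.04), Trub1 (0.28 ± 0.04), Il1rap (0.20 ± 0.03), Mxi1 (0.35 ± 0.05), which encodes a repressor that competes with Myc for its partner Max, Trnt1 (0.23 ± 0.03), Wdr3, the nucleolar gene Gnl3, Atp23, Psmd8 and Hdgf (0.17 to 0.35). The sphingosine phosphate receptor gene S1pr3 had the largest t in size among the falling genes (-1.02 ± 0.12, adjusted p = 9.69e-06), followed by Rgs3 (-0.30 ± 0.04), Emilin1 (-0.32 ± 0.04), the apoptosis regulator Cflar (-0.35 ± 0.05), Vamp5, Prkra, Tmem51, Il21r, Sulf1, Agpat4, Serpina10 and Rasgrp3 (-0.75 to -0.23).

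Markers of T cells moved with the Myc level: all 7 fell, by slopes from -1.14 ± 0.22 for Cd3g (adjusted p = 0.000654) to -0.33 ± 0.08 for Icos (adjusted p = 0.00254). Interferon genes (8 of 10), NF-kB genes (8 of 10), with Nfkb2 (-0.47 ± 0.07, adjusted p = 0.000117) having the lowest p, germinal centre genes (3 of 4), with Bcl6 (-0.83 ± 0.13, adjusted p = 0.000135), mature B cell genes (5 of 14) and plasma cell genes (2 of 5) fell too. With an estimated correlation none of these lists passed, with an adjusted p of 0.271 for interferon, 0.127 for NF-kB, 0.127 for germinal centre, 0.293 for mature B cell and 0.271 for plasma cell genes. Myc target genes rose in 7 of 17, with Gnl3 (0.17 ± 0.03, adjusted p = 7.84e-05) and Cad (0.20 ± 0.05, adjusted p = 0.00616), and proliferation genes in 4 of 18. With arrays shifted by the reference genes, 5 Myc target genes and 2 proliferation genes rose. The camera adjusted p was 3.31e-07 for the T cell list with a preset correlation and 0.127 with an estimated correlation, and 8.41e-05 and 0.293 for the Myc targets. With a preset correlation the NF-kB, interferon, germinal centre, mature B cell, myeloid, endothelial and plasma cell lists were also placed lower (adjusted p from 3.05e-07 to 0.0398). Precursor B cell genes (3 of 13), myeloid genes (2 of 13), Bcl2 family genes (2 of 11), and 1 gene each of the stroma, endothelial, hypoxia, early stress and p53 target lists fell, 1 oxidative phosphorylation gene and 1 reference gene rose, and 0 glycolysis genes and 0 genes shared by B cell stages passed. The medians of the glycolysis and reference lists changed sign with arrays shifted by the reference genes. The Myc count rested in large part on tumours 2 and 24: it was 1185 without tumour 2 and 1467 without tumour 24, 413 without both, and 485 with the score of other cell types as a covariate. With arrays shifted by the reference genes 26.3% of the associated genes rose in place of 51.9%.

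With the level of Cdkn2a, limma found 0 genes at the adjusted threshold over all 32 tumours, and 490 of 11226 at an unadjusted p under 0.05. The robust and trended version also found 0, with 491 at an unadjusted p under 0.05. The count was 1 without tumour 31 and 1 with arrays shifted by the reference genes. Within the 29 tumours of the lower Cdkn2a cluster the count was again 0, with 1178 genes at an unadjusted p under 0.05. With a preset correlation, camera placed the stroma (adjusted p = 0.00285) and endothelial (adjusted p = 0.0373) lists lower and the Myc target (adjusted p = 0.003) and glycolysis (adjusted p = 0.0194) lists higher. With an estimated correlation the adjusted p was 0.638 for each of the 4. The p53 target list had a median slope of 0.01 where camera placed it down, and the hypoxia list a median of -0.02 with a mean of 0.02.

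The first 3 components of the expression values held 20.2%, 12% and 10.6% of the variance. Their signs are arbitrary. Of 60 relations between these components and the list scores 23 passed the adjusted threshold. Values are given for the 6 with the largest r in size on the first component, the 2 largest on the second and all on the third. The first component followed the NF-kB score (r = 0.92, raw p = 1e-05, adjusted p = 0.0001; rho = 0.76, p = 1e-05), the early stress score (r = 0.81, adjusted p = 0.0001; rho = 0.75, p = 2e-05), the T cell score (r = 0.74, adjusted p = 0.0001; rho = 0.67, p = 6e-05) and the myeloid score (r = 0.73, adjusted p = 0.0001; rho = 0.68, p = 2e-05). It ran against the Myc target score (r = -0.80, adjusted p = 0.0001; rho = -0.66, p = 4e-05) and the proliferation score (r = -0.74, adjusted p = 0.000257; rho = -0.54, p = 0.0016). The raw p was 3e-05 for the proliferation score and 1e-05 for the others. Without the 2 far tumours these r were 0.89, 0.73, 0.49, 0.62, -0.71 and -0.63. The second component followed the precursor B cell score (r = 0.61, raw p = 0.00023, adjusted p = 0.00153; rho = 0.63, p = 0.00017) and ran against the mature B cell score (r = -0.62, raw p = 0.0002, adjusted p = 0.0015; rho = -0.50, p = 0.00357), with r of 0.62 and -0.55 without the 2 far tumours. The third ran against the T cell score (r = -0.54, raw p = 0.00183, adjusted p = 0.00687; rho = -0.44, p = 0.0114), a relation that rested on the 2 far tumours, with r = -0.25 without them. It also followed the precursor B cell score (r = 0.44, raw p = 0.0134, adjusted p = 0.0365; rho = 0.39, p = 0.0308), with r = 0.42 without the 2 far tumours, and ran against the plasma cell score (r = -0.53, raw p = 0.00186, adjusted p = 0.00687; rho = -0.48, p = 0.00611), with r = -0.56 without the 2 far tumours.

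Genes of a whole chromosome shifted together in single tumours, an analysis chosen after the data were seen. For each of 20 chromosomes and each tumour, the median over the chromosome's tested genes of the deviation from the gene's median over tumours was taken, with 11205 genes placed. Of 640 such medians, 31 exceeded 0.15 in size, in 20 tumours, and the other 12 tumours had none. Chromosome 3 was up in 9 tumours (7, 8, 10, 12, 15, 18, 22, 27 and 32) and chromosome 15, which carries the Myc gene, in 5 (13, 16, 17, 20 and 31). The Myc level in those 5 was between 11.16 and 11.69, inside the range of all 32 tumours (9.81 to 12.30). Chromosome 12 was up in tumours 6, 16, 20 and 32, chromosome 18 in 6, 12 and 19, chromosome 10 in 17 and 20, and chromosome 16 in 12 and 17. Chromosomes 5, 6 and 17 were up in 1 tumour each, namely 7, 1 and 10. The 28 upward shifts were between 0.18 and 0.36. The 3 downward shifts were chromosome 19 in tumour 14 (-0.59), chromosome 13 in tumour 23 (-0.40) and chromosome 4 in tumour 28 (-0.27). The largest of the other medians was 0.121 in size.

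**Figure D4:**
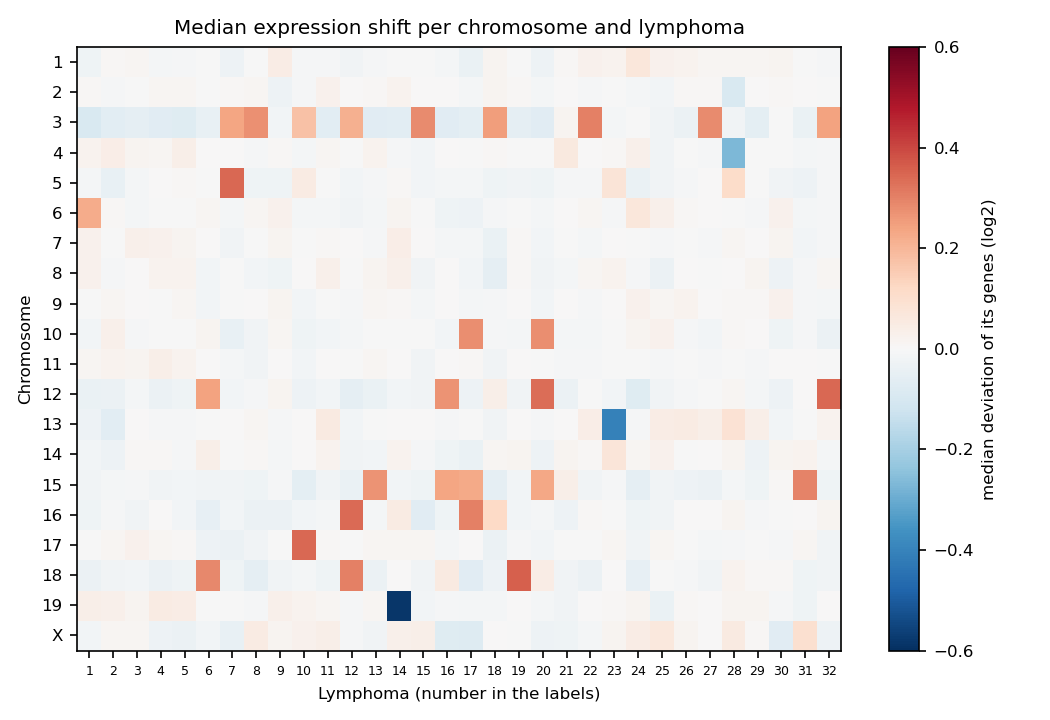
Median over each chromosome's tested genes (y axis) of the log2 deviation from the gene's median over all tumours, for each of the 32 lymphomas (x axis), with red above and blue below 0. Chromosome 3 was up in 9 tumours, and the largest downward shift was -0.59 for chromosome 19 in tumour 14.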

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

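The values without the 11 tumours of the upper Bpifa2 cluster, without the 2 tumours with the highest T cell score and without the 3 of the upper Cdkn2a cluster were chosen after the data were seen. No paired analysis was possible because the labels give 1 group only. The following counts leave aside the omission of single tumours. Of the main results' values under an alternative, 235 kept their side of the threshold or moved by less than their bound. A relation that passed in neither setting was placed there even if its sign changed. Another 14 passed the threshold where the reported value did not, and 11 no longer passed. A further 18 counts moved by more than 1.5 times, some of them over fewer genes, relations or tumours. In 1 relation the sign changed with a pass in at least 1 of the settings. The relations of stroma with endothelial genes, of germinal centre with NF-kB genes, of Myc targets with proliferation and of Bcl2 with Mcl1 passed wherever they could be computed. Of the 24 named genes on each of the precursor, proliferation and Myc axes, Ankrd37 alone lost its call, under 2 alternatives, and none did when single tumours were left out. These genes were picked for the largest t in the same data, so their calls do not show how stable the other associated genes were. Signal over background limits genes with dim probe sets, and with the filter at the 75th percentile 12 of the 20 relations could be computed. With the score of other cell types 13 could, since relations that use a part of that score were left out, and with the first component 18. Except where fewer genes or tumours were used, the cause was not tested.

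The filter at the 75th percentile, which tests fewer genes, left 146 genes with an SD over 1, and 4 of the 12 relations that could be computed passed. Under it 2057 of 6798 genes were associated with proliferation and 1408 of 6814 with Myc. In the main setting these were 3126 of 11209 and 2257 of 11226, so the lower counts go with fewer genes tested. Under it Cdkn2a with p53 targets had r = 0.39 and no longer passed, and interferon with myeloid genes had r = 0.46 and passed. The SD from the median absolute deviation left 236 genes over 1. Without a filter, precursor with mature B cell genes (r = -0.40), proliferation with p53 targets (r = -0.42) and oxidative phosphorylation with glycolysis (r = 0.38) passed. With arrays shifted by the reference genes, proliferation with p53 targets (r = -0.39), interferon with myeloid genes (r = 0.45) and oxidative phosphorylation with glycolysis (r = 0.45) passed, 1613 genes were associated with proliferation and 1 with Cdkn2a. With arrays quantile normalized again, proliferation with p53 targets passed (r = -0.39). With the 3' minus 5' difference as a covariate, precursor with mature B cell genes (r = -0.39) and proliferation with p53 targets (r = -0.41) passed.

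With the score of other cell types as a covariate 4 of the 13 relations that could be computed passed, and Myc with its targets did not (r = 0.34). Under it 410 genes were associated with the precursor score, 1287 with proliferation and 485 with Myc. With the first component as the list score, precursor with mature B cell genes (r = -0.50), proliferation with p53 targets (r = -0.41) and oxidative phosphorylation with glycolysis (r = 0.43) passed, and hypoxia with glycolysis changed sign and passed (r = -0.52). By Spearman's rho 6 relations passed, and the T cell score with myeloid genes (0.42), pan-B cell genes (-0.30) and proliferation (-0.32) and stroma with early stress genes (0.32) did not. Ranks of the axis gave 1822 genes with proliferation and 1176 with Myc. Without the upper Bpifa2 cluster, which leaves fewer tumours, stroma with early stress genes did not pass (r = 0.18), and 156 genes were associated with the precursor score and 1743 with proliferation. Without the 2 tumours with the highest T cell score, Myc with its targets (r = 0.42) and the T cell score with myeloid genes (r = 0.15), pan-B cell genes (r = -0.22) and proliferation (r = -0.18) did not pass, oxidative phosphorylation with glycolysis did (r = 0.50), and 952 genes were associated with the precursor score and 413 with Myc.

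Leaving out each tumour in turn, r ran from -0.44 to -0.26 for precursor with mature B cell genes, from -0.17 (without tumour 24) to 0.44 (without tumour 2) for Ighm with mature B cell genes, from -0.45 to -0.26 for proliferation with p53 targets, from 0.26 (without tumour 24) to 0.54 for T cell with myeloid genes, from 0.31 (without tumour 30) to 0.50 for stroma with early stress genes, from 0.33 to 0.46 for interferon with myeloid genes, from 0.23 to 0.45 for oxidative phosphorylation with glycolysis, from -0.60 to -0.36 (without tumour 24) for pan-B with T cell genes, and from -0.57 to -0.35 (without tumour 24) for T cell genes with proliferation. The counts ran from 337 to 396 genes for an SD over 1, from 125 (without tumour 31) to 385 for the precursor score, from 2264 to 3571 for proliferation, from 0 to 1 (without tumour 31) for Cdkn2a and from 1185 (without tumour 2) to 2901 for Myc, with 1467 without tumour 24.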

Other observations

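The tests of the salivary genes, of the NF-kB score against the Myc target score and of the chromosomes were chosen only after the most variable genes and the components had been seen. Their bounds were written before their values were seen, except that the form of the salivary and pancreas values was changed later. Tumour 2 stood apart in germinal centre genes. It was the highest of the 32 tumours in 8 of the 9 measured genes of that list, with Fas highest in tumour 24. Rgs13, a regulator of G protein signalling found in germinal centre B cells, was 11.93 in tumour 2 and at most 5.19 in the others. Bcl6 was 10.90 against a next highest value of 8.11, Mef2b 9.92 against 5.99, Mybl1 8.99 against 5.89, and Gcsam 7.82 against 4.39. Tumour 2 was also the highest in the complement receptor gene Cr2 (10.20, with 7.20 next) and in Jchain (12.93, with 11.82 next), and the lowest in Ighm (9.64) and Myc (9.81). T cell markers were high in it as well: it was the highest in Cd4, Cd8a and Cd8b1, and Cd3g was 10.64 and Cd3d 10.67, both second to tumour 24. Tumour 24 was the highest in 9 of the 12 measured T cell genes, in 3 of 4 NK cell genes, in 8 of 11 NF-kB genes and in 8 of 16 mature B cell genes.

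Genes of fat cells, chosen for a description after the data were seen, varied together. The 7 genes had a mean pairwise r of 0.78 over the tumours, from 0.61 to 0.95. Adipoq, which encodes a hormone secreted by fat cells, ran from 4.09 in tumour 22 to 11.21 in tumour 19, and Car3 from 4.25 in tumour 22 to 13.41 in tumour 19. Lpl, Cidec, Retn and Plin4 were also highest in tumour 19, and Fabp4 was highest in tumour 30. Tumour 29 was highest in 4 of 7 measured plasma cell genes, among them Sdc1 (10.67, with 9.73 next) and Prdm1 (8.83, with 8.55 next), but lowest of the 32 in Jchain (3.31), and the highest plasma cell score was that of tumour 2.

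The 9 salivary genes among the 25 most variable (Bpifa2, Amy1, Smr3a, Car6, Pip, Dnase1, Cst10, Dcpp3 and Scgb1b27) were set against 19 other salivary markers, of which 9 had a median at or above the filter level in the other 21 tumours and 0 are in another list. Within the 11 tumours of the upper Bpifa2 cluster the mean score of the markers followed those genes (r = 0.929, p = 0.00011, and rho = 0.955, p = 3e-05, two-sided permutation tests). Within the 21 of the lower cluster it did not (r = 0.154, p = 0.509, and rho = 0.142, p = 0.541, same tests). Most of the named genes were dim there, such as Smr3a (4.21 to 4.73) and Pip (4.21 to 4.71), though Dcpp3 was 6.56 to 7.06. A relation could therefore hardly show in the lower cluster, and its absence carries no weight. Not every marker was raised: Klk1 was 7.20 to 7.88 in the upper and 7.30 to 7.98 in the lower cluster, and Smr2 6.25 to 6.83 and 6.51 to 7.04. Of the 19 markers, Lpo and Dcpp1 alone were higher in every tumour of the upper cluster than in any of the lower. The others overlapped, such as Bhlha15, with 6.30 to 10.70 in the upper and 5.75 to 10.65 in the lower cluster. The bound had been written for r over all 32 tumours, which also exceeded it, and r was taken within clusters once these were seen. Salivary gland tissue taken along with the lymphoma is therefore a candidate source of these transcripts in the 11 tumours. Pancreas tissue, which also makes amylase, is argued against in the 3 tumours with the highest Bpifa2, since there 12 enzyme genes lay at most 0.0728 above their medians, as the median over these genes, a form of the value settled after their mean had been seen, with both under the bound of 0.5, while tumour 29, also in the upper cluster, had the highest value of all tumours (0.348).

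The NF-kB score ran against the Myc target score across tumours (r = -0.81 and rho = -0.72, with p = 1e-05 for both, the smallest that the permutations can give). Without tumours 2 and 24, the 2 farthest from the median NF-kB score, r was -0.77. This pair was not a planned relation. It was chosen after the scores had been seen to run opposite along the first component (r = 0.92 and -0.80), so its unadjusted p-value does not weigh chance. As far as the measures below capture them, admixed T cells and myeloid cells, RNA degradation and a lower share of B lineage cells are each argued against as the whole cause. The partial r was -0.719 with the T cell and myeloid scores held fixed, -0.805 with the 3' minus 5' difference and -0.856 with the score of genes shared by B cell stages. That last score does not separate lymphoma cells from normal B cells, so the share of normal B cells was not tested. A difference between tissue and dissociated cells as the source of RNA stays open, since the labels do not give it for each tumour.

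The chromosome shifts did not arise from the placement of genes by chance: 0 of 100 shufflings of the genes over the chromosomes gave as many pairs of tumour and chromosome as the 31 found, and the highest count among the shufflings was 0. The proximal and distal parts of the chromosome both moved the same way by more than 0.1 in 96.8% of the pairs (30 of 31). The exception was chromosome 3 in tumour 10. These pairs had been selected by the median over the whole chromosome, which a change in only part of it would move less. The share was thus set in part by the selection, and it cannot tell how often only part of a chromosome changed. Gain or loss of a whole chromosome may account for the shifts in these pairs, but no DNA measurement was used here to test it. The share of cells that would carry such a change was not estimated. In tumour 28 the parts of chromosome 4 differed, with -0.10 in the proximal and -0.48 in the distal part.

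Chance pairing of tumours and axis values was tested with 61 orders of the values, the real one included. With 60 random orders the highest other count was 101 for the precursor score, 3 for proliferation and 3 for Myc, where the real counts were 259, 3126 and 2257, so 1 order of 61 gave as many genes for each of these axes. As far as 61 orders allow, chance pairing is argued against for proliferation and Myc over all 32 tumours. For the precursor score the same holds for all 32 tumours only: without tumour 31 (125 genes) and without the upper Bpifa2 cluster (156 genes) no orders were drawn, and these counts lie near 101. None were drawn for the Myc counts of 413 and 485 either. Each axis was read from the same arrays as the genes. The orders therefore cannot tell an axis from any other along a main component. The proliferation score had r = -0.74 with the first component. For Cdkn2a, where limma gave 0 genes (490 at an unadjusted p under 0.05, and 0 with robust and trended eBayes), all 61 orders gave as many, and the highest other count was 34. The labels give 1 group, so no difference between groups was tested as an explanation of any of these patterns.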
